A study of Saccharomyces cerevisiae W303 with 28 samples.

How the data were processed

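Chromatin immunoprecipitation sequencing (ChIP-seq) of Scc1, the kleisin subunit that closes the cohesin ring, was read from 28 libraries of budding yeast of the W303 background: 14 immunoprecipitates (IP) and the 14 whole-cell extracts (input) that belong to them. Each library was taken from its labels to a tag (HA, Pk or none), a genotype, a break state and a nocodazole state. One label conflict was found: the HA strain whose title calls the cut site uncleavable carries a treatment entry for break induction, and the title was followed. Its extract showed no loss at the break, as given with the results. Replicate numbers were taken from the labels where given. The Pk, untagged and HA no-break titles give none, and these libraries were set to replicate 1. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

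The deposited signal was taken as read coverage in windows of 1 kb, 12447 windows on 16 chromosomes, the same in every library, without a header. Bowtie2, SAMtools, bedtools and MACS2 are named in the submitters' processing notes, with no versions or roles. The series description states that the ChIP experiments were calibrated with Candida glabrata. In the deposited signal of each extract the smallest value above 0 was 1, so these are coverage values with no scaling. In each IP library the smallest value above 0, which ran from 0.0535 to 6.20, was taken as coverage by 1 read. Division by that step gave IP coverage in reads, so the IP depths below rest on this assumption. A mean over all bases of a window could fall below 1 read. How bases without reads were counted is thus not known, and low depths may be overstated. The genome build is not given in the sources used here. The last gene in the R64 gene table lay past the last window on 2 chromosomes, and 7 chromosomes were longer than that gene by over 20 kb, so the builds differ. For this reason no gene, replication-origin or mating-type coordinate was placed, and coordinates below are those of the deposited windows. Gene lists, gene orientation classes, ribosomal DNA and named loci that had been planned were not analysed here.

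Each IP value was divided by its own extract, with the extract first set relative to its own median. The plan had been to divide by the extract as deposited. Since the extracts proved to be unscaled coverage, that division would have put their sequencing depth into the calibrated IP, and it was run instead as an alternative chosen after seeing the data. Windows with a mean relative extract of 0.25 to 4 over the HA libraries were kept (11638 windows). Per window, log2 of IP over extract was taken after adding 5% of each library's median to both as a pseudocount, so a fold on this scale understates changes of low windows. Per region, log2 of the mean IP over the mean relative extract was taken with no pseudocount. The genome level of a library is its median over kept windows. Values called relative to the library median have that level subtracted.

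The rule fixed before the data were examined used the window with the lowest ratio of break to no-break extracts. If that window lay within 20 kb of the URA3 locus on chromosome 5, the break was to be put at URA3, otherwise at the window. As no gene was placed, the URA3 step was left out, a departure from that rule. The break was put at the centre of the 5-window running mean with the lowest ratio. This was the window at chromosome 5, 119001 to 120000. The flank was defined as 5 to 50 kb on both sides, and distance classes were set on each side. The class at 0 to 5 kb left held fewer than 3 kept windows and was left out, which leaves 13 classes. Centromeres were approximated by the highest 21-window running mean of Scc1 on each chromosome in the no-break library of the other tag, and a pericentromere reached 15 kb to each side of it. The maxima of both tags lay within 2 kb of each other on 15 of 16 chromosomes. Arms excluded the outer 20 kb and everything within 100 kb of the break.

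Comparisons among the 9 HA IP libraries used limma (version 3.58.1 in R 4.3.3) with 5 group means, 4 residual degrees of freedom and Benjamini-Hochberg adjustment, once over windows and once over 92 regions. A threshold of 0.05 was used. The single no-break library was assumed to vary like the other groups. The prior degrees of freedom were infinite in both fits, so every region shared one spread. An alternative with each region's own residual spread (no moderation) was therefore added after seeing the data. Genome levels of 2 libraries against 2 were compared by a two-sided exact permutation test, whose smallest p is 0.33. Pk groups had 1 library each and were not tested. Their flank difference was placed among 9922 random flanks of the same shape elsewhere in the genome, out of 10000 drawn. Named regions followed a rule fixed before the data were examined: windows past the threshold were joined when at most 2 kb apart, and the 10 largest increases and 10 largest decreases were listed. For the Pk pairs the 10 highest and 10 lowest windows were listed.

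On simulated data with 200 of 11638 windows changed by a log2 of 2, the window fit recovered 92.0% for break against no break, 98.0% for rad17 against wild type, 98.5% for pds5 against wild type and 99.0% for each of the other 2 comparisons. At a log2 of 1 it recovered 15.0% for break against no break and 27.5% to 35.5% for the others. The region fit recovered 10 of 10 changed regions of a log2 of 1.5 in each comparison, with at most 1 false call among 92 regions.

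Alternatives fixed before the data were examined were centring each library on its median, the IP signal alone, other pseudocounts, filters, window sizes, flank and pericentromere widths, leaving out each replicate, and the replicate number as a block. Those added after seeing the data were the extract as deposited, the IP alone with centring, no moderation, subtraction of the untagged IP, and comparisons of each mutant with the no-break wild type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

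Median IP coverage per window ran from 2.29 reads (Pk without nocodazole) to 82.0 reads, and median extract coverage from 43.6 to 112 reads. Coverage of overlapping reads does not give independent counts, so no counting interval was computed. No pair of libraries held identical values.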

Results

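Scc1 was mapped 4 h after galactose addition in cells with a site-specific DNA double-strand break, in most cases under nocodazole, which holds cells in mitosis by removing microtubules. The series concerns the part cohesin plays in the search for homologous DNA during repair. HA-tagged Scc1 was measured with a break and nocodazole in wild-type, rad17, pds5 and rad17 pds5 cells (n = 2 libraries each) and without a break in wild-type cells (n = 1). Rad17 is a subunit of the DNA damage checkpoint clamp, and Pds5 is a cohesin-bound regulator of its loading and release. The strains called pds5 and rad17 pds5 here are pds5-AID and rad17 pds5-AID in the titles, a degron allele. The labels do not mention auxin, so the extent of depletion is not known here. Pk-tagged Scc1 was measured once each in wild type with a break and no nocodazole, wild type without a break, wild type with a break, and rad17 with a break, the last 3 with nocodazole. An untagged strain with a break and nocodazole served as the background (n = 1).

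Median IP coverage per window was 82.0 and 65.5 reads in HA wild type with a break, 46.8 and 62.0 in rad17, 54.2 and 66.5 in pds5, 25.9 and 70.6 in rad17 pds5, and 62.0 without a break. For Pk it was 50.5 reads in wild type with a break, 43.3 in rad17 and 9.28 without a break. The Pk library without nocodazole held 2.29 reads, and 7.17% of its windows stood at its smallest value above 0, taken as 1 read. The untagged library held 36.7 reads. Replicates correlated across windows with Pearson's r of 0.953 to 0.981. Replicate 2 lay above replicate 1 in all 4 replicated groups, by a median log2 of 0.16 to 0.50.

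DNA around the cut site was lost in every library labelled as cut. Within 5 kb of the break, the 12 extracts with a break kept 10.3% to 24.7% of the coverage of the no-break extracts, and at 5 to 10 kb they kept 26.7% to 37.9%. At 10 to 15 kb they kept 51.5% to 72.6%. The 2 no-break extracts stood at 98.9% and 101% of their common mean within 5 kb. No window had each of the 5 rad17 extracts under 50% of each of the 9 others, so a deletion was not seen and the extracts gave no check of the rad17 label. In 3 extracts (both no-break strains and HA wild type with a break, replicate 2) coverage was uneven along the genome, with an SD of log2 coverage of 0.456 to 0.737 against 0.211 to 0.261 in the other 11. Their patterns correlated with one another at r = 0.881 to 0.933 across windows, which are not independent replicates.

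**Figure D1:**
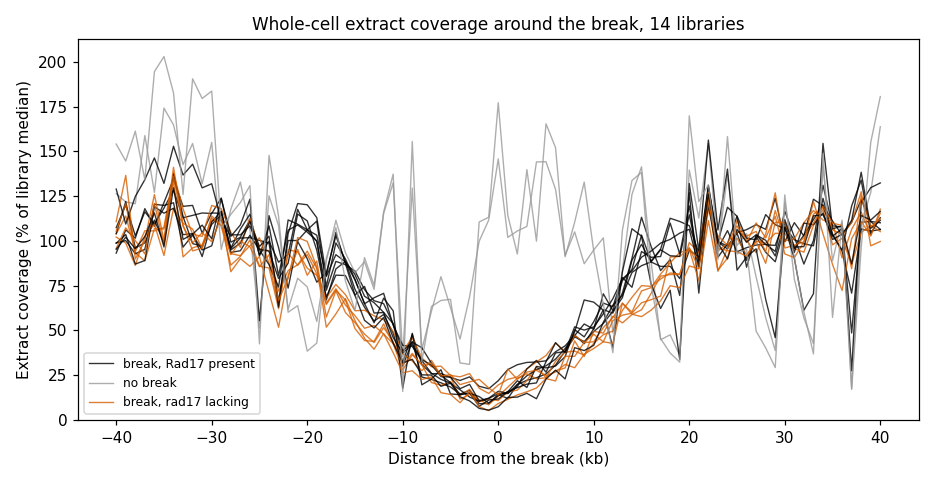
Coverage of the whole-cell extract in 1-kb windows around the break on chromosome 5, as a percentage of each library's median (vertical axis) against distance in kb (horizontal axis), 1 line per library (14 libraries). The 12 break libraries fall towards the break, to 10.3% to 24.7% of the no-break level within 5 kb, and the 2 no-break libraries do not.

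The untagged IP gave the background. Its genome level was 0.99 on the log2 scale, against 4.05 in HA wild type with a break and 3.93 without, and HA wild type with a break stood 8.33-fold above it. The level of rad17 was 5.76-fold, of pds5 5.58-fold and of rad17 pds5 3.40-fold above the untagged level. Untagged signal was not flat. It was 1.61-fold above its own genome level over the 16 pericentromeres and 1.37-fold at 5 to 10 kb right of the break. Its highest break class was 30 to 50 kb right, inside the flank, at 1.79-fold, with 1 window at 33 kb at a log2 of 3.97 over the extract relative to the library median.

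The first comparison asked where cohesin changes when the chromosome is cut. With a break, HA-tagged Scc1 per DNA rose by a log2 of 2.67 ± 0.33 (SE) at 5 to 10 kb left of the break and by 3.02 ± 0.33 at 5 to 10 kb right of it (limma, adjusted p = 5.58e-13 and 5.52e-16), that is, 6.36-fold and 8.11-fold. The left class went from 4.16 (n = 1) to 6.83 ± 0.25 (SD, n = 2), and the right class from 3.23 to 6.25 ± 0.20. The rise was 1.19 at 10 to 20 kb left, 1.21 at 20 to 30 kb and 1.09 at 30 to 50 kb (adjusted p = 0.00713, 0.00713 and 0.0171). To the right it was 0.82 at 10 to 20 kb (adjusted p = 0.161). At 20 to 30 and 30 to 50 kb right, where the cohesin maximum of chromosome 5 lies 37 kb from the break, the differences were -0.20 and -0.30 and did not pass the test. The planned flank of 5 to 50 kb on both sides, which includes that maximum, differed by 0.55 ± 0.33 (adjusted p = 0.601). Without the pericentromere it rose by 1.303 (adjusted p = 0.00236).

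The amount of IP signal itself rose less. With the IP signal alone, the rise was 1.19 left and 1.43 right at 5 to 10 kb (adjusted p = 0.00565 and 0.000698), and the class at 0 to 5 kb right went from a rise of 2.25 over the extract to -0.48 (adjusted p = 0.907). With each region's own residual spread the adjusted p was 0.272 left and 0.207 right at 5 to 10 kb, and 0.796, 0.796 and 0.481 in the 3 classes from 10 to 50 kb left, of which the one at 30 to 50 kb also missed the threshold with the IP alone (0.73, adjusted p = 0.270). Relative to the library median the differences were 2.54 and 2.89, with adjusted p = 0.0370 and 0.00580 on each region's own spread.

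The 2 largest increases among 195 joined regions lay beside the break on chromosome 5, at 119001 to 135000 (peak 3.18 ± 0.48) and 105001 to 115000 (3.01 ± 0.50). Others of the 10 largest lay on that chromosome at 83001 to 96000 (1.87 ± 0.48), 201001 to 204000 (1.79), 184001 to 185000 (1.68), 175001 to 176000 (1.54) and 68001 to 78000 (1.53). The remaining 3 were on other chromosomes: chromosome 12, 593001 to 595000 (1.99), chromosome 3, 1 to 10000 (1.88), and chromosome 4, 1457001 to 1459000 (1.68). In all, 287 windows rose and 289 fell of 11638. The falls were led by chromosome 4, 443001 to 444000 (-2.72), which lies 5 kb from the cohesin maximum, and chromosome 2, 407001 to 408000 (-2.31). With the IP signal alone only 24 windows rose and 3 fell. Of the 10 listed rises, 6 then missed the threshold, all on chromosome 5, among them 105001 to 115000 (1.31, adjusted p = 0.238). None of the listed falls passed, and 9 of the 10 listed falls then had differences between -0.21 and 0.25. Centred on the library medians, 765 rose and 1482 fell. Only 1 window changed over the extract as deposited, where the flank differed by -0.12 (adjusted p = 0.909). Without HA wild type replicate 1 the total went from 576 to 31 windows. It was 271 without either rad17 pds5 library, and 1185 and 1187 without pds5 replicate 1 and 2.

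Pericentromeres did not gain with the break. Over all 16 the difference was -0.31 ± 0.33 (adjusted p = 0.797), from -0.46 on chromosome 6 to -0.17 on chromosome 9. Relative to the library median they fell by 0.44 ± 0.10 (adjusted p = 0.00758), and 15 of the 16 single ones passed, though on each region's own spread the adjusted p over all was 0.0551. The genome level differed by 0.13, within the SD of 0.14 between the wild-type replicates, with 1 library on the other side and no test.

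**Figure D2:**
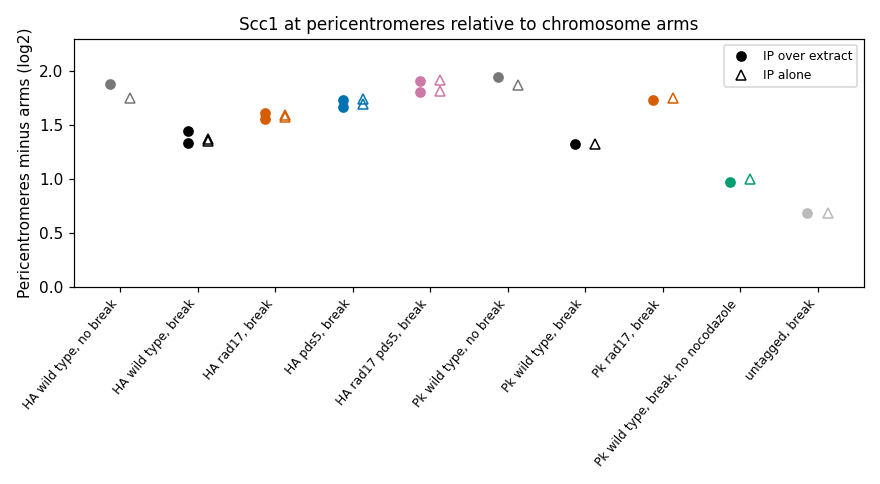
Mean log2 Scc1 signal of the pericentromeres minus that of the chromosome arms (vertical axis), 1 point per library, over the extract (circles) and for the IP alone (triangles). It is 1.33 and 1.45 in HA wild type with a break and 1.89 without, a measure added after seeing the data.

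The Pk-tagged pair, which shares no library with the HA set, differed by 2.68 at 5 to 10 kb left (3.58 to 6.26) and by 3.13 right (2.87 to 6.01). With the IP alone these Pk differences were 1.16 and 1.54, and that at 0 to 5 kb right went from 2.51 over the extract to -0.21. All 10 of the highest Pk windows over the extract lay within 14 kb of the break, led by chromosome 5, 126001 to 127000 (3.41). Its lowest window was the one on chromosome 4 at 443001 to 444000 (-3.06). The flank differed by 0.49, at percentile 99.9 of random flanks, whose central 95% ran from -0.13 to 0.41. The Pk genome level itself was higher by 0.41 with the break, and relative to it the flank differed by 0.08. Pericentromeres differed by -0.33. Across the 13 break classes the HA and Pk differences correlated at r = 0.992 (Spearman 0.978). Across 197 windows within 100 kb of the break r was 0.908 (Spearman 0.855). Over the 11441 other windows r was 0.685 over the extract and 0.365 with the IP alone. Windows and neighbouring classes are not independent replicates. There is no replicate check on the Pk values, and both no-break extracts share the uneven pattern.

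**Figure D3:**
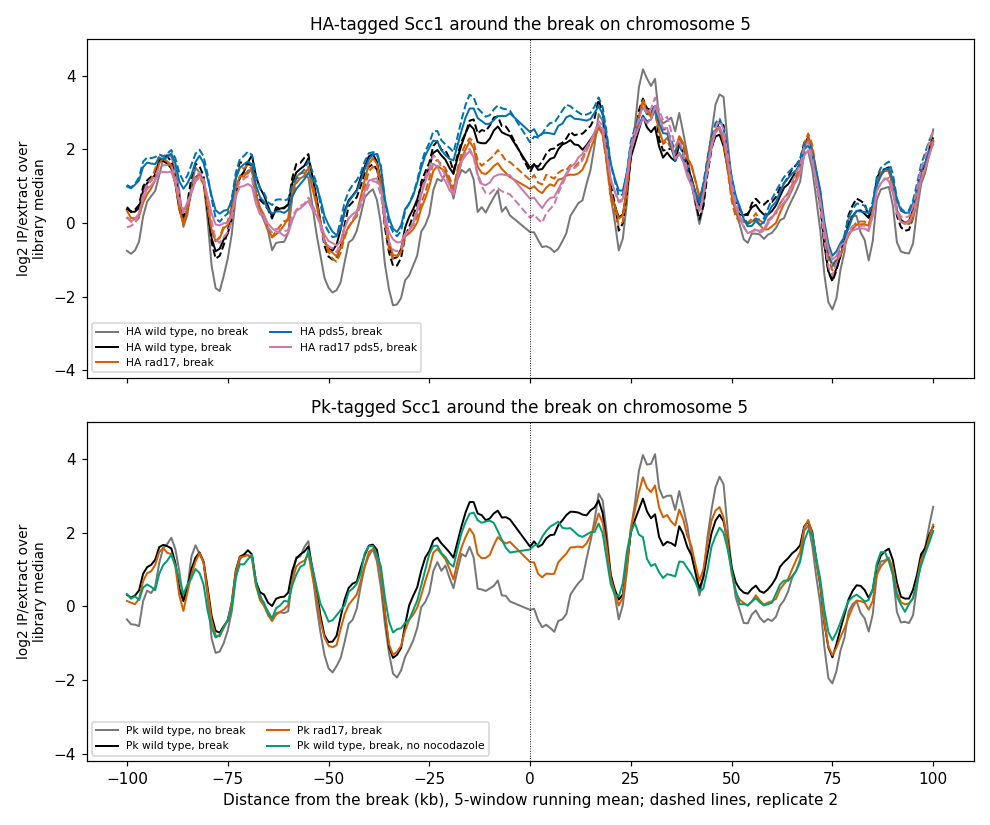
Scc1 around the break, as log2 of IP over extract relative to the library median (vertical axis) against distance in kb (horizontal axis), 1 line per library and a colour per group. Averaged over 5 to 10 kb right, the no-break library lies lowest of its tag, at -0.69 in HA, against 2.24 and 2.16 in the HA wild-type libraries with a break.

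The second comparison asked whether Scc1 beside the break is lower without the checkpoint clamp. No mutant was measured without a break, so a smaller gain cannot be told from a lower level before the cut. In rad17 cells with a break, Scc1 was lower than in wild type by 1.38 ± 0.27 at 5 to 10 kb left (5.45 ± 0.57 against 6.83 ± 0.25, SD, n = 2 each). On the right it was lower by 1.32 ± 0.27 (4.93 ± 0.35 against 6.25 ± 0.20). The adjusted p-values from limma were 5.60e-05 and 6.98e-05, and the levels were 0.385 and 0.399 of wild type. The classes at 0 to 5 kb right (-1.06), 10 to 20 kb left (-0.93), 20 to 30 kb left (-1.0001) and 10 to 20 kb right (-0.90) also fell. At 20 to 50 kb right and over the pericentromeres (-0.22 ± 0.27) no fall passed the test. The flank of 5 to 50 kb differed by -0.57 ± 0.27 (adjusted p = 0.152). It passed with the IP alone (-0.70, adjusted p = 0.0458), without the pericentromere (-0.95, 0.00740) and at 5 to 20 kb (-0.97, 0.00608). It passed too with the replicate number as a block, though whether the numbers pair the samples was left open. Relative to the library medians the flank levels were close, 1.95 ± 0.009 in rad17 against 1.98 ± 0.03 in wild type (SD, n = 2 each). Scc1 of rad17 cells still stood above the no-break wild type, by 1.29 left and 1.69 right (adjusted p = 0.00531 and 4.92e-05, a comparison added after seeing the data), though on each region's own spread the adjusted p was 0.782 for both, and with the IP alone these differences were -0.37 and -0.34.

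The genome level of rad17 was 3.52 ± 0.21 against 4.05 ± 0.14, a difference of -0.53 with exact permutation p = 0.33 (two-sided, n = 2 each), the smallest possible. Relative to that level the falls at 5 to 10 kb were 0.84 and 0.79 (adjusted p = 0.0166 and 0.00262, or 0.122 and 0.113 on each region's own spread), while the pericentromeres were higher by 0.32 (adjusted p = 0.0224, or 0.113 on each region's own spread). With each region's own spread no break class passed (adjusted p = 0.276 at 5 to 10 kb on both sides). The falls there missed the threshold without rad17 replicate 1 (-0.97 and -1.08) and without wild-type replicate 2 (-1.20 and -1.19, adjusted p = 0.0569 for both).

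Of single windows, 628 fell, 39 of them within 100 kb of the break, and 2 rose. With the IP alone 78 fell, 43 of them within 100 kb of the break, and 4 rose. The 2 that rose were chromosome 13, 754001 to 755000 (1.97 ± 0.30), and chromosome 4, 461001 to 462000 (1.21 ± 0.30). The largest falls included chromosome 15, 1029001 to 1030000 (-2.65 ± 0.39), chromosome 4, 1456001 to 1462000 (-2.28 ± 0.38), chromosome 3, 12001 to 19000 (-2.01), and chromosome 5, 106001 to 115000 (-1.99) and 120001 to 133000 (-1.72). Of these, the one on chromosome 3 missed the threshold with the IP alone (-0.92, adjusted p = 0.145) and centred (0.205), and the last one centred (0.0769). Of all 10 listed falls, 5 passed with the IP alone and 5 centred. Since no gene was placed, whether any listed region lies at the altered RAD17 locus was not checked. Relative to the library medians 19 windows rose and 8 fell. The division by the extract as deposited left 0 called by limma (84 at an unadjusted p under 0.05). The count of 630 became 2 without wild-type replicate 2, the library with the uneven extract, 5 without rad17 replicate 1 and 132 without rad17 replicate 2. It was 229 and 225 without rad17 pds5 replicate 1 and 2, and 1653 and 1668 without pds5 replicate 1 and 2.

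Pk-tagged Scc1 in rad17 differed from wild type by -0.91 at 5 to 10 kb left and by -1.32 right. Its pericentromeres differed by 0.21 and its genome level by -0.28. The flank difference of -0.25 stood at percentile 3.58 of random flanks, inside their central 95% (-0.26 to 0.08), and relative to the library medians it was 0.03. The highest Pk window was again chromosome 13, 754001 to 755000 (1.98), and the lowest again chromosome 15, 1029001 to 1030000 (-1.77). Of the 10 lowest Pk windows, 4 lay within 100 kb of the break. Across the 13 break classes the tags correlated at r = 0.928 (Spearman 0.929). Over the 197 windows within 100 kb r was 0.685 (Spearman 0.694), and over other windows 0.317 (Spearman 0.283).

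The third comparison asked what differs in pds5 cells. Next to the break, Scc1 of pds5 cells was as high as in wild type within the error: the difference was -0.14 ± 0.27 left and 0.17 ± 0.27 right at 5 to 10 kb (adjusted p = 0.622 and 0.546), with 6.69 ± 0.55 and 6.42 ± 0.57 (SD, n = 2) in pds5. Of 31 arm regions 28 fell (median -0.72) and of 30 chromosome ends 28 fell (median -1.22). Over the 16 pericentromeres the difference was -0.38 ± 0.27 (adjusted p = 0.210), and it passed with the replicate number as a block. The fall of the arms depended on the setting: on each region's own spread limma called 0 of 31 arms (14 at an unadjusted p under 0.05) and 19 of 30 ends, and relative to the library medians 3 arms fell (median -0.14). The flank of 5 to 50 kb differed by -0.21 ± 0.27 (adjusted p = 0.454). The genome level was 3.47 ± 0.34 against 4.05 ± 0.14, a difference of -0.58 (exact permutation p = 0.33, n = 2 each).

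Relative to the genome level, pds5 cells had more Scc1 on the flank, by 0.36 ± 0.08 (adjusted p = 0.00366), and by 0.75 at 5 to 10 kb right (adjusted p = 0.000256), and less at 26 of 30 chromosome ends. In windows, 3889 fell and 5 rose over the extract set relative to its own median, and 1010 rose and 1609 fell relative to the library medians. Over the extract as deposited, as first planned, limma called 0 (999 at an unadjusted p under 0.05). The largest falls were at chromosome 2, 5001 to 14000 (-3.08 ± 0.42), chromosome 16, 311001 to 330000 (-2.98 ± 0.42), chromosome 7, 105001 to 118000 (-2.86 ± 0.40), chromosome 15, 1001 to 28000 (-2.70), chromosome 5, 476001 to 484000 (-2.70), and chromosome 11, 64001 to 92000 (-2.65) and 2001 to 21000 (-2.62). The 5 rises were single windows of 0.62 to 0.89, of which 2 passed with the IP alone and 2 lay on chromosome 5 (41001 to 42000 and 32001 to 33000). The total of 3894 was 616 without wild-type replicate 2, 902 without pds5 replicate 1 and 6182 without pds5 replicate 2.

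Next to the break, rad17 pds5 cells held far less Scc1 than pds5 cells. At 5 to 10 kb the level of rad17 pds5 was 3.99 ± 0.17 left and 3.77 ± 0.14 right (SD, n = 2), below pds5 by 2.70 ± 0.27 and 2.65 ± 0.27 (limma, adjusted p = 3.63e-19 and 9.74e-19), that is, 0.154 and 0.159 of it. The fall was 3.05 at 0 to 5 kb right, 1.97 at 10 to 20 kb left, 1.45 at 20 to 30 kb left and 1.39 at 30 to 50 kb left. The class at 0 to 5 kb right passed the extract filter only through the no-break extract. The flank of 5 to 50 kb fell by 1.15 ± 0.27 (adjusted p = 0.000250), and relative to the library medians by 0.43 ± 0.08 (adjusted p = 0.00285). With each region's own spread the classes at 5 to 10 kb still passed (adjusted p = 0.0410 for both) and the flank did not (0.0802). The flank missed the threshold too over the extract as deposited, as first planned (-1.19, adjusted p = 0.140). The pericentromeres differed by -0.52 ± 0.27 (adjusted p = 0.0638), from -0.63 on chromosome 5 to -0.46 on chromosome 4, and 5 of the 16 single ones fell. With the replicate number as a block the difference over all 16 passed. On each region's own spread limma called 0 of the 16 (0 at an unadjusted p under 0.05), and relative to the library medians the direction turned, to a median of 0.20 (0.08 to 0.25).

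The genome level was lower by 0.71 (2.76 ± 0.17 against 3.47 ± 0.34, exact permutation p = 0.33, n = 2 each). The 2 largest of 1031 joined falls flank the break: chromosome 5, 119001 to 143000 (-3.12 ± 0.38), and chromosome 5, 1001 to 115000 (-2.82 ± 0.40), which spans 109 windows past the threshold. Others among the 10 largest were chromosome 16, 494001 to 500000 (-2.26), chromosome 15, 1024001 to 1030000 (-2.03), chromosome 4, 1456001 to 1474000 (-1.81), and chromosome 5, 170001 to 217000 (-1.51). All 10 listed falls passed with the IP alone and 4 when centred, without those on chromosome 4 and at 170001 to 217000 (adjusted p = 0.0996 and 0.148). Only 2 windows rose, on chromosome 3, 28001 to 29000 (0.87), and chromosome 6, 89001 to 90000 (0.80). In all 3530 windows fell, 160 of them among the 197 within 100 kb of the break. Relative to the medians 41 windows fell, 37 of them within 100 kb of the break, and 5 rose. With division by the extract as deposited 9 fell. The total of 3532 was 51 and 341 without rad17 pds5 replicate 1 and 2, 79 and 9144 without pds5 replicate 2 and 1, and 1879 and 1894 without wild-type replicate 1 and 2.

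Against rad17 alone, rad17 pds5 cells had less Scc1 in every class of region. All 16 pericentromeres, all 31 arms, all 30 chromosome ends and all 13 break classes fell. The falls over the pericentromeres (-0.68 ± 0.27, adjusted p = 0.0139) and the flank (-0.79 ± 0.27, adjusted p = 0.00486) were near the difference in genome level of -0.76 (2.76 ± 0.17 against 3.52 ± 0.21, exact permutation p = 0.33, n = 2 each). Relative to that level neither differed (0.08 and -0.03, adjusted p = 0.431 and 0.745). Relative to it 26 of 30 chromosome ends, 21 of 31 arms and 8 of 13 break classes fell, among them 0 to 5 kb right (-0.86, adjusted p = 0.00197), 50 to 75 kb left (-0.51, 0.000746) and 5 to 10 kb left and right (-0.70 and -0.39, 0.0109 and 0.0113). On each region's own spread these had adjusted p = 0.0467, 0.0172, 0.0945 and 0.0699. Without that centring, own spread gave adjusted p = 0.103 for the pericentromeres, of which 1 of 16 single ones passed, and 0.0766 for the flank. Both missed the threshold without rad17 pds5 replicate 1 (-0.46 and -0.60) and without rad17 replicate 2 (-0.51 and -0.63).

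In windows, 7170 fell and 2 rose over the extract set relative to its own median, and 1488 fell and 482 rose relative to the library medians. Over the extract as deposited 798 fell, and the flank differed by -0.96 (adjusted p = 0.0720). The largest falls were chromosome 13, 754001 to 785000 (-3.55 ± 0.30), chromosome 16, 493001 to 500000 (-3.16), chromosome 2, 1 to 39000 (-3.06), chromosome 7, 103001 to 127000 (-2.86), chromosome 13, 2001 to 30000 (-2.84), and chromosome 8, 557001 to 565000 (-2.80). The 2 that rose were chromosome 11, 47001 to 48000 (1.01), and chromosome 6, 89001 to 90000 (0.84). The total of 7172 was 1754 without rad17 replicate 2 and 1775 without rad17 pds5 replicate 1.

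**Figure D4:**
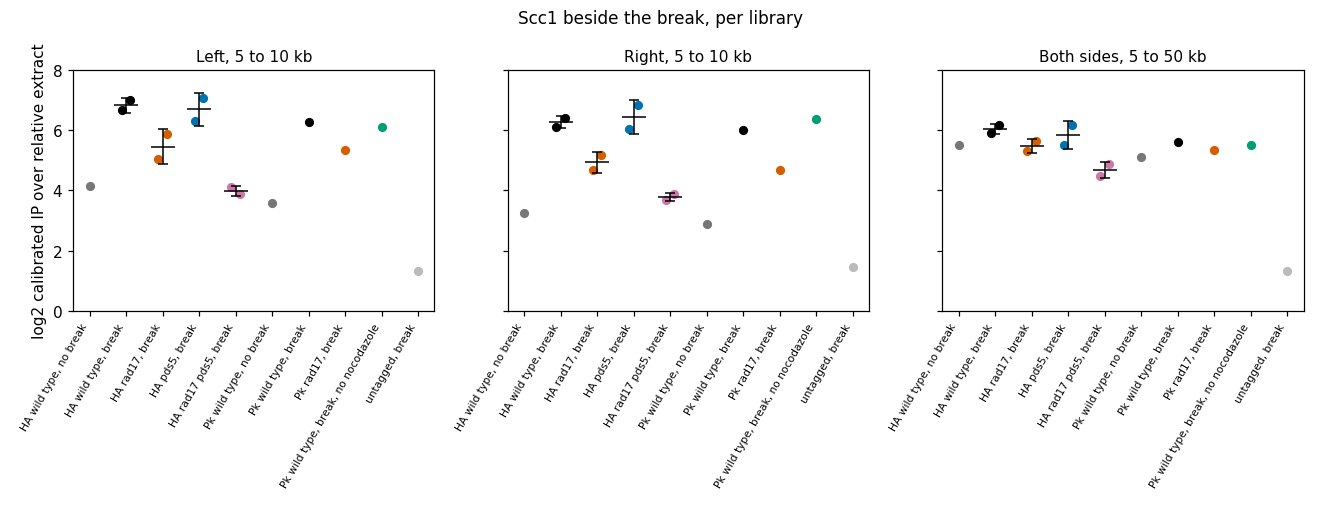
Log2 of calibrated IP over relative extract per library (points) at 5 to 10 kb left and right of the break and over the flank of 5 to 50 kb. Bars give the mean and SD where n = 2. At 5 to 10 kb left, rad17 pds5 lies at 3.99 and the no-break library at 4.16, below pds5 at 6.69.

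Whether loss of Rad17 acts differently in pds5 cells was tested as an interaction. The fall due to rad17 was larger in pds5 cells by 1.32 ± 0.38 at 5 to 10 kb left, by 1.32 ± 0.38 at 5 to 10 kb right and by 1.99 ± 0.38 at 0 to 5 kb right (adjusted p = 0.0193, 0.0193 and 3.33e-05). The windows at 0 to 5 kb right passed the extract filter only through the no-break extract, which has no part in the interaction. In pds5 replicate 2 their extract stood at 7.34% to 14.8% of the library median, so this class rests on very little DNA. Over the flank of 5 to 50 kb the interaction was -0.58 ± 0.38 (adjusted p = 0.695), and over the pericentromeres -0.30. The flank interaction passed with the replicate number as a block, though whether the numbers pair the samples was left open. Among windows 2 passed, on chromosome 13, 754001 to 755000 (-2.81 ± 0.42), and chromosome 1, 192001 to 193000 (-1.50 ± 0.33). The window on chromosome 13 also passed with the IP alone (-2.61) and centred (-2.63), and the one on chromosome 1 in neither (-0.54 and -1.32, adjusted p = 0.995 and 0.728). In limma, 0 windows passed over the extract as deposited (104 at an unadjusted p under 0.05). Relative to the library medians limma called 7 of the 13 break classes. It called 0 of 16 pericentromeres, 31 arms and 30 chromosome ends (0, 0 and 3 at an unadjusted p under 0.05). The near classes no longer passed on each region's own spread (adjusted p = 0.728), nor with the IP alone (-0.99, -0.89 and -1.23, adjusted p = 0.208, 0.338 and 0.0759). At 5 to 10 kb they were lost in 6 of the 8 fits without one library, and kept only without rad17 replicate 1 or pds5 replicate 1.

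Compared with the no-break wild type (added after seeing the data), Scc1 at 5 to 10 kb was higher by 2.53 left and 3.19 right in pds5 cells with a break (limma, adjusted p = 6.22e-12 and 1.07e-17). On each region's own spread the adjusted p was 0.0679 and 0.0627, and with the IP alone the differences were 1.09 and 1.31. In rad17 pds5 cells with a break it differed by -0.17 and 0.54 (adjusted p = 0.619 and 0.108), and with the IP alone it fell by 1.46 and 1.35 (adjusted p = 1.77e-05 and 5.78e-05). Relative to the library medians it was higher in those cells too, by 1.00 and 1.70 (adjusted p = 0.00629 and 1.91e-05, or 0.119 and 0.00922 on each region's own spread).

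The last comparison, of nocodazole against none in Pk wild type with a break, rests on 1 library each, and the one without nocodazole was very shallow. Next to the break the values differed by 0.14 left (6.26 against 6.11) and by -0.35 right (6.01 against 6.36) at 5 to 10 kb. Pericentromeres differed by 0.14 and the flank by 0.08, at percentile 98.95 of random flanks, whose median was -0.20. The random flanks were not matched for pericentromeres. Classes of the flank ran from -0.37 at 30 to 50 kb left to 0.38 at 30 to 50 kb right, which overlaps the pericentromere. None of the 10 highest or 10 lowest windows lay within 100 kb of the break. The highest, chromosome 2, 334001 to 335000, differed by 5.12 and the lowest, chromosome 11, 238001 to 239000, by -2.86, in a library whose median window held 2.29 reads.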

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

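Of the tests below, centring for the interaction, the left-out extract for the loss of DNA, and every test of the distant sites, including their split by chromosome, were chosen only after the result was seen. The 3 distant sites were first noticed while values of both tags were on view.

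A test of the difference between the effects of rad17 in pds5 and in PDS5 cells passed for the classes at 5 to 10 kb left (-1.32), 0 to 5 kb right (-1.99) and 5 to 10 kb right (-1.32) of the break. It also passed for the window at chromosome 13, 754001 (-2.81), and the window at chromosome 1, 192001 (-1.50), which are given as values. The second did not pass with the IP alone (-0.54, adjusted p = 0.995).

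For the 3 classes, whose mean interaction was -1.54 (SE 0.54 from their own residuals), background and calibration were weighed. With the untagged signal subtracted the mean was -1.73 (SE 0.55), and with each library centred on its own median -1.36 (SE 0.29), both further from 0 than the -0.5 set as the limit. With the IP alone it was -1.04 (SE 0.28), also past that limit. The class at 0 to 5 kb right passed the extract filter only through the no-break extract. The 3 classes were picked because they passed in these same libraries, which favours a mean past the limit in each setting. These values therefore exclude none of the explanations. With the IP alone the 3 single calls did end, since the differences shrank while the SE hardly moved, and on each region's own spread none passed (adjusted p = 0.728). A biological difference between the genotypes stays open and untested, beside the chance spread of 2 libraries per group.

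A signal in data outside the Scc1 comparisons was the loss of DNA in the extracts. At 10 to 20 kb from the break, the 5 nocodazole extracts lacking Rad17 kept less DNA than the 6 with Rad17, by a log2 of -0.30 (exact permutation p = 0.00216, n = 5 and 6). This p is the smallest the test can give. Both sets hold replicate pairs of the same HA strains, which the permutation treats as independent. Its p-values here thus understate the uncertainty between strains. Without the wild-type extract of uneven coverage the difference was -0.32 (exact permutation p = 0.00794, n = 5 and 5). That extract stood at -0.225, below the mean of -0.136 of the 6, so it had narrowed the gap. Leaving it out could only widen the gap, so this is no test of uneven coverage. With all extracts, the difference was -0.0933 at 20 to 30 kb (exact permutation p = 0.00216, n = 5 and 6). At 60 to 100 kb it was -0.0386 (SE 0.0115), though this also had exact p = 0.00216 (n = 5 and 6). Within 5 kb it was 0.19 (exact p = 0.403, n = 5 and 6). The value at 60 to 100 kb is too small for a strain difference along the chromosome to account for that at 10 to 20 kb. Longer resection without Rad17 is a hypothesis that was not tested here, since coverage does not measure resection length. A measure of single-stranded DNA along both sides in the same strains would test it, and other differences between the strains stay open.

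The 3 joined regions away from chromosome 5 among the 10 largest HA rises with a break were also weighed. With the IP alone, relative to the library medians, the Pk difference between break and no break averaged 0.72 (SE 0.47 over the 3 sites): 1.52 on chromosome 3, 0.75 on chromosome 4 and -0.09 on chromosome 12. On chromosomes 3 and 4 both Pk values, of libraries that had no part in the rule for the sites, lie above the limit of 0.3. In those libraries the rise was thus seen without division by the extract. They are single libraries with no spread, and the limit was set after they were seen. The HA difference of 1.26 (SE 0.17) there comes from the libraries that picked the sites. On chromosome 12 HA gave 0.44 (SE 0.43). On chromosomes 3 and 4, the rises of both tags with the IP alone argue against division by the extract as the source. Each tag has only 1 no-break library there. On chromosome 12 division by the extract stays open as the source. Each break extract kept 85.5% or more of no break at the sites on chromosomes 3 and 4, against a second cut with loss of DNA there. On chromosome 12 the mean was 58.0% (lowest 43.6%, and 73.9% for the lowest mean over the 3 sites), as a second cut there predicts. The reference, however, is the 2 uneven no-break extracts. The uneven extract with a break, HA wild type replicate 2, kept 74.8% there, the highest of the break extracts. Uneven coverage therefore stays open beside a second cut and was not tested apart from it.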

How the results depend on the processing

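Over 40 results and 477 alternatives, 352 kept their direction and their side of the threshold (or stayed within the stated range), 59 moved, 24 newly passed, 27 no longer passed and 15 turned their sign. Many alternatives left out a library outside the comparison. The size of a region difference could not change there, only its spread, and genome levels could not change at all. This raises the count of 352. Chosen after seeing the data were the extract as deposited, the IP alone with centring, no moderation, subtraction of the untagged IP and comparisons with the no-break wild type. Groups of 2, a lone no-break library and a shared spread limit every call, and the Pk library without nocodazole is limited by its depth of 2.29 reads. Where a library was left out, the lone one was assumed to vary like the other groups. Except where stated, the cause was not tested.

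With each library centred on its median, the genome-level difference is removed by construction. Windows changed were 2247 for break against no break, 27 for rad17, 46 for rad17 pds5 against pds5 and 1970 for rad17 pds5 against rad17. The flank of break against no break (0.42) and its pericentromeres (-0.44) newly passed. Signs turned for the pericentromeres of rad17 (0.32), pds5 (0.20), rad17 pds5 against pds5 (0.20) and against rad17 (0.0784), and for pds5 on the flank (0.36) and at 5 to 10 kb left (0.44). They also turned for the flank of Pk rad17 (0.0327), and against no break for rad17 (0.38) and rad17 pds5 (0.35). The flank of pds5 against no break (0.79) newly passed, and that of rad17 pds5 against rad17 (-0.0312) no longer did.

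With the IP alone, windows changed were 27 for break against no break, 82 for rad17, 5895 for rad17 pds5 against pds5 and 5 for the interaction. The rad17 flank (-0.70) and the pericentromeres of rad17 pds5 against pds5 (-0.53) newly passed, and pds5 at 5 to 10 kb right turned its sign (-0.12). With the IP alone and centred the windows were 103, 110, 130, 3746 (rad17 pds5 against rad17) and 19 (interaction).

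With the extract as deposited, as first planned, windows changed in limma were 1 for break against no break, 0 for rad17 (84 at an unadjusted p under 0.05), 0 for pds5 (999), 9 for rad17 pds5 against pds5, 798 against rad17 and 0 for the interaction (104). The flank was -0.12 for break against no break, a turned sign, and -1.19 and -0.96 for rad17 pds5 against pds5 and rad17, neither past the threshold (limma, adjusted p = 0.140 and 0.0720). With no moderation these last 2 flanks (-1.15 and -0.79) did not pass either.

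With a pseudocount of 20%, windows changed were 128 for break against no break, 413 for rad17 and 5516 for rad17 pds5 against pds5. In 5-kb windows, of which there are fewer by construction, they were 13, 31, 1307 (pds5), 1461 (rad17 pds5 against pds5) and 1937 (against rad17). The flank newly passed for break against no break and for rad17 at 5 to 20 kb (1.47 and -0.97), on the left alone (1.28 and -0.93) and without the pericentromere (1.303 and -0.95). At 5 to 20 kb the Pk flank was 1.58 for the break and -0.89 for rad17. Pericentromeres of 25 kb to each side newly passed for rad17 pds5 against pds5 (-0.55).

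With the replicate number as a replicate block, windows changed were 5011 for rad17, 6772 for pds5, 10286 for rad17 pds5 against pds5 and 17 for the interaction. The flank of rad17 (-0.57) and of the interaction (-0.58), and the pericentromeres of pds5 (-0.38) and of rad17 pds5 against pds5 (-0.52), newly passed. Whether the numbers pair the samples was left open. The labels name no shared batch or day, and replicate differences of 2 groups correlated across windows at r = 0.0844 to 0.341, over 0.1 in 5 of 6 pairs of groups, with replicate 2 above replicate 1 in all 4. With the IP alone r was 0.46 for wild type with rad17 and 0.411 for pds5 with rad17 pds5. The remaining pairs lay between -0.054 and 0.0591.

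Leaving out each HA library with a break in turn gave 31 to 1187 windows for break against no break, 2 to 1668 for rad17, 616 to 6182 for pds5, 51 to 9144 for rad17 pds5 against pds5, 1754 to 8262 against rad17, and 0 to 3 for the interaction. The 0 arose in limma without rad17 pds5 replicate 1 (192 windows at an unadjusted p under 0.05). The flank ranged from 0.43 to 0.67 for break against no break, -0.73 to -0.41 for rad17, -0.55 to 0.12 for pds5, -1.48 to -0.81 for rad17 pds5 against pds5, -0.98 to -0.60 against rad17 and -0.91 to -0.25 for the interaction. Without either pds5 replicate the rad17 flank newly passed (-0.57). Pericentromeres ranged from -0.44 to -0.18, -0.38 to -0.05, -0.69 to -0.0765, -0.82 to -0.21 and -0.90 to -0.46 in the same order of 5 comparisons. At 5 to 10 kb left and right, the ranges were 2.50 to 2.84 and 2.88 to 3.16 for break against no break, -1.78 to -0.97 and -1.57 to -1.08 for rad17, -0.52 to 0.25 and -0.23 to 0.57 for pds5, -3.08 to -2.31 and -3.05 to -2.25 for rad17 pds5 against pds5, -1.86 to -1.05 and -1.40 to -0.91 against rad17, and -1.73 to -0.92 and -1.73 to -0.92 for the interaction. For pds5 at 5 to 10 kb left the sign also turned without wild-type replicate 2 (0.04). Genome levels ranged from 0.03 to 0.23, -0.68 to -0.38, -0.82 to -0.34, -0.96 to -0.47 and -0.91 to -0.61.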

Other observations

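The contrast between pericentromeres and arms, a measure chosen after seeing the data, was 1.89 in HA wild type without a break and 1.33 and 1.45 with one. In Pk it was 1.95 without a break, 1.32 with one, 1.74 in rad17 with a break and 0.97 without nocodazole. In HA with a break it was 1.56 and 1.61 in rad17, 1.67 and 1.74 in pds5, and 1.81 and 1.91 in rad17 pds5. The untagged library gave 0.69.

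Windows were also ranked by Pk signal without a break into 10 equal groups, a measure chosen after seeing the data. The difference in Scc1 between the top and bottom groups was lower in the 4 HA libraries of pds5 strains than in the 4 others with a break, 3.35 ± 0.20 against 3.89 ± 0.15 (SD, exact permutation p = 0.0286, n = 4 each, the smallest possible). With the IP alone the difference was -0.39 (exact p = 0.0286, n = 4 each), and with the untagged signal subtracted -0.13 (exact p = 0.429, n = 4 each). Each side holds replicate pairs of the same strains, which the permutation treats as independent.

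At the distant sites, Scc1 relative to the library median in the 4 HA libraries lacking Rad17 minus that in the 4 others with a break was -0.53 on chromosome 3, -1.10 on chromosome 4 and 0.34 on chromosome 12. No p is given, since 2 of those 4 others are the wild-type libraries whose rise picked the sites.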
